A study of Homo sapiens with 2 samples.

How the data were processed

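Gene expression was measured in MCF7, an estrogen receptor positive human breast cancer cell line, after 6 h with 10 µM of the compound NSC620358 or with its solvent, dimethyl sulfoxide (DMSO). The series held 2 arrays, 1 per group, with no replicates. Per the labels' protocols, total RNA was purified with a Qiagen spin column kit, and biotin-labelled, fragmented cRNA was made from it as Affymetrix prescribes for expression arrays.

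The deposited table held 1 signal intensity per probe set and array. A probe set is a group of short probes for the same transcript. Per the submitters' processing notes these intensities came from MAS5, Affymetrix's summary of a probe set's perfect match and mismatch probes; its version is not given in the sources used here. The values were positive and on a linear scale, and the mean after trimming 2% of the probe sets at each end was 500.1 on both arrays. The deposited intensities were therefore used without further scaling. Scanner files and detection calls were not analysed here. Both columns of the table belonged to samples of the series. The labels do not say whether the arrays were run together, so array run and treatment cannot be told apart.

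Probe sets were named through the platform's gene annotation, with symbols brought up to date by gene ID in the RefSeq table of GRCh38.p14. Of 54675 probe sets, 41097 named 1 gene, 1801 named several and 11777 named none; 41043 symbols were matched by gene ID. No gene was named from a probe set with several genes. A gene's value was that of its probe set with the highest mean log2 signal, which gave 19775 genes. The floor was the median of all signals on both arrays, 66.2. A gene was measured when its larger signal reached the floor, and signals below the floor were set to it. A ratio with 1 array below the floor is therefore a lower bound and is written as "at least". RefSeq coordinates served only for gene spans and neighbours, because the deposited table names no genome build.

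With 1 array per group there was no test, and no p-value was computed. Genes were described by a fold rule, at least 2-fold higher or lower with NSC620358. The spread between different probe sets of a gene was taken as a technical reference, and it does not replace a spread between replicates. For 29 gene lists with 595 entries, the median log2 ratio of the measured members was placed among the medians of 10000 random lists of the same size. The random lists were matched on mean log2 signal in 20 bins. A list was called apart in the outer 2.5% on either side, as a description of these arrays. Tested on simulated data with 12974 genes, the fold rule called 16% of genes changed 1.5-fold, 40% of those changed 2-fold, 98% of those changed 4-fold and 100% of those changed 8-fold, with 50 genes of each size. It also called 225 of 12774 unchanged genes, or 1.76%. Noise was drawn for each probe set alone, sized by the spread between probe sets of a gene on these arrays. That noise held no difference between whole arrays, cultures or runs. The 1.76% is therefore not a rate of false calls for NSC620358 against DMSO. In the same simulation 4 of 100 unshifted lists of 20 genes were called apart, and all 100 lists shifted by 0.5 on the log2 scale were called higher. These lists were random draws from the genes that they were ranked against. They do not show how often a list of genes that move together would be called apart.

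The lists, the fold rule, the floor, the alternatives except those named below and the rule for named genes were fixed before the data were examined. That rule took the 12 highest and the 12 lowest ratios among genes above the floor on both arrays, provided that the gene's other probe sets above the floor had the same sign. It also took the 5 largest bounds in each direction, the 4 measured members of each list with the largest absolute ratio, and 14 genes that were always named. It named 145 genes; HSPA1A was on it but had no probe set of its own. Alternatives were median centring, quantile normalisation and a loess correction of the ratio on signal, other floors, no floor, a pseudocount, other ways to pick probe sets, and other fold thresholds. Scaling to the poly-A spike-ins, scaling to the hybridisation controls (each to the same median log2 signal of those probe sets on both arrays) and leaving out members shared between lists were added after the data were seen. Gene families in the closing section were also chosen after the ratios were seen.

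Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 (loess with a span of 0.4) and matplotlib 3.10.9 were used.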

Results

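The series asked which genes differ in expression in MCF7 cells, a human breast cancer cell line, after 6 h with 10 µM NSC620358 compared with DMSO alone. NSC620358 is known here only by its code and is described by the submitters as active on spheroids, which are ball-shaped cell cultures. The data were 2 arrays, 1 with NSC620358 and 1 with DMSO, each with 54675 probe sets. The median signal was 61.3 with DMSO and 71.1 with NSC620358, and 48.4% and 51.6% of probe sets lay at or above the floor of 66.2. Log2 signals of the 24413 probe sets above the floor on both arrays correlated with a Pearson r of 0.961, across probe sets that are not independent replicates. No value below has a replicate, so none of the differences has a replicate check, and the number of arrays limits the precision.

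The 12 highest ratios with NSC620358 included members of the heat shock, ATF4, immediate early and NRF2 lists. HSPA6, an inducible HSP70 chaperone, had a signal of 69.5 with DMSO and 4600 with NSC620358, a log2 ratio of 6.05. DDIT3, which encodes the stress transcription factor CHOP, went from 246 to 13213, a log2 ratio of 5.75. The immediate early gene FOS went from 334 to 11735 (5.14), and HMOX1, the heme-degrading oxygenase, from 212 to 3900 (4.20). The other genes among the 12 highest ratios were HSPA1L (5.77), PPP1R15A (4.40), ATF3 (4.37), ACTRT3 (4.32), CHAC1 (4.30), DNAJB4 (3.82), MICB (3.73) and ZFAND2A (3.69). PPP1R15A encodes a stress-induced phosphatase subunit, and its other probe set gave 4.51. The other probe sets of ATF3 gave 0.37 to 2.67. Among genes below the floor with DMSO, ARC was at least 23.1-fold higher, FOSB at least 14.9-fold, MUC5B at least 9.36-fold, RFPL2 at least 6.78-fold and RGS2 at least 6.07-fold.

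The lowest ratios were smaller in size. SYDE2 went from 551 to 73.4, a log2 ratio of -2.91, and BRI3BP from 6095 to 1067, a log2 ratio of -2.51. TRIM25, a ubiquitin ligase, and the zinc finger gene ZNF652 both had -2.42, GPAM, an enzyme of triglyceride synthesis, had -2.32, and ATP13A3 had -2.22. GK5 (-2.09), CMTM4 (-1.97), C8orf88 (-1.96), USP46 (-1.96), the TGF-beta receptor gene TGFBR1 (-1.92) and SMC5 (-1.86) followed. Their other probe sets above the floor on both arrays had smaller ratios, such as -0.53 for TRIM25 and -0.04 for SMC5. Among genes below the floor with NSC620358, KLHL23 was at least 3.32-fold lower, LINC01210 at least 3.16-fold, PAIP2B at least 3.04-fold, CAVIN1 at least 2.76-fold and SLC38A12 at least 2.74-fold. The other probe set of CAVIN1 above the floor gave 0.54.

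**Figure D1:**
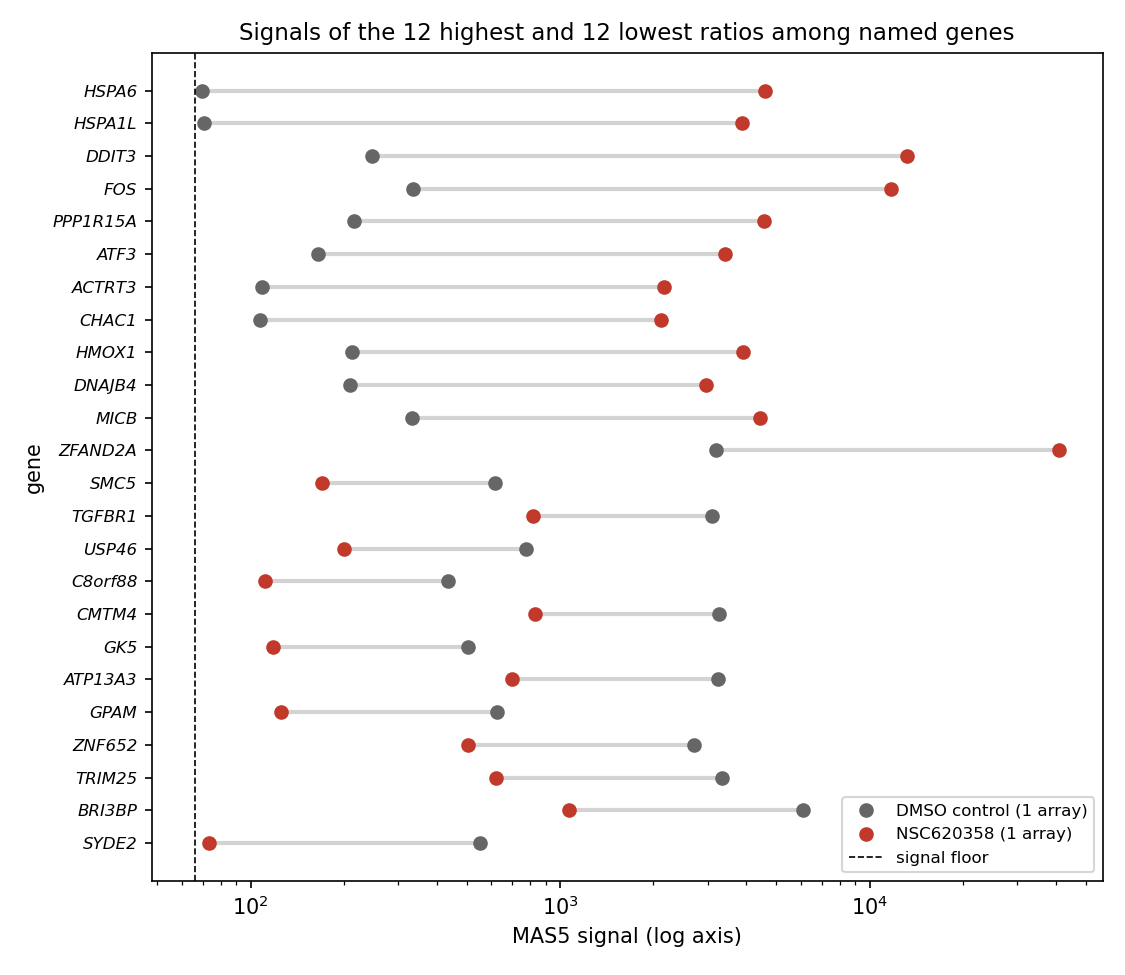
MAS5 signal (log axis) of the 12 genes with the highest and the 12 with the lowest ratios under the rule for named genes, with DMSO (grey) and NSC620358 (red), 1 array each; the dashed line is the signal floor of 66.2. HSPA6 lies at 69.5 and 4600, and SYDE2 at 551 and 73.4 as deposited, without scaling to spike-in controls.

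Of 13411 measured genes, 577 (4.30%) were at least 2-fold higher with NSC620358, 310 (2.31%) at least 2-fold lower, and 12524 neither. Of the genes above the floor on both arrays, 443 were higher and 278 lower, and 55 were at least 4-fold higher against 7 at least 4-fold lower. The SD of log2 ratios was 0.42 between probe sets of the same gene (15012 probe sets of 5574 genes), and it was 0.51 at the lowest signals (67.1 to 215) and 0.32 at the highest (1509 to 62174). The split of calls depended on the floor and the scaling. Higher genes were 65.1% of calls as deposited, 49.7% (172 higher, 174 lower) with the floor at the 75th percentile of signals, 15.1% (193 higher, 1081 lower) with the arrays scaled to the hybridisation controls and 1.99% (85 higher, 4177 lower) with the poly-A spike-ins. The median log2 ratio of all measured genes was 0.11 as deposited, -0.29 with the hybridisation controls and -0.77 with the poly-A spike-ins, so directions below are relative to the other genes on the arrays. The labels do not say that equal amounts of spike-ins were added.

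Heat shock genes, which encode chaperones, were higher together: 7 of 20 measured members were at least 2-fold higher and none lower, and all 20 had a log2 ratio above 0. Beside HSPA6, HSPA1L and DNAJB4, the co-chaperone gene DNAJB1 went from 7619 to 40903 (2.42). The list's median of 0.84 lay above all 10000 random lists, whose middle 95% spanned -0.05 to 0.26. It did so after quantile normalisation (0.79) and loess (0.80) too. With the poly-A spike-ins the median itself was -0.06, with 6 members higher and none lower. HSPA1A, the best known member, had only probe sets shared with relatives, and cross-hybridisation of HSPA6 and HSPA1L probes with it was not tested.

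Targets of ATF4, the transcription factor of amino acid and translation stress, were higher in 9 of 25 measured members and lower in none. DDIT3, PPP1R15A, ATF3 and CHAC1 led them. The median was 0.71, above all random lists (-0.10 to 0.22). With the poly-A spike-ins it was -0.23, with 6 members higher and 3 lower. Genes of the unfolded protein response of the endoplasmic reticulum did not stand apart. Of 19 measured members, HERPUD1 alone passed 2-fold (1.41), the chaperone gene HSPA5 had 0.42, PDIA4 0.85, SEL1L -0.85 and EDEM1 -0.52. Their median was -0.08 and their mean 0.04, at percentile 6.99 of random lists. HERPUD1 was below 2-fold with the hybridisation controls (0.98) and the poly-A spike-ins (0.47), and with the latter 10 members were lower and none higher, with a median of -1.02.

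Immediate early genes, which respond within minutes to hours to many stimuli, were higher in 14 of 27 measured members and lower in none. FOS, ATF3, FOSB and the phosphatase gene DUSP2 (2.68) had the highest ratios, while MYC had 0.19. The median of 1.16 was above all random lists (-0.11 to 0.25) and stayed above 0 with the poly-A spike-ins, at 0.22, with 10 members higher and 2 lower. Short-lived transcripts were higher in 6 of 22 members, led by IER5 (2.63), KLF6 (2.26), SOCS3 (2.09) and JUN (1.97). TOB1, picked out after its value was seen, was the 1 lower member (-1.17). Their median was 0.56, at percentile 100, and -0.38 with the poly-A spike-ins, where 4 were higher and 4 lower. Of the 22, 11 were also in at least 1 other list, most of them among the immediate early genes, and without those the remaining list was no longer apart, at percentile 97.2.

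Targets of the tumour suppressor p53 were higher in 5 of 23 members: GADD45A (2.79), GDF15 (2.33), PMAIP1 (1.65), SESN2 (1.36) and CDKN1A (1.32), which encodes the cell cycle inhibitor p21. POLH, picked out after its value was seen, was the 1 lower member (-1.12). GDF15, SESN2 and PMAIP1 each had 1 other probe set above the floor, with 0.02, 3.28 and 2.15. The median was 0.53, above all random lists (-0.14 to 0.27), and the call was lost without probe sets that can match several transcripts. With the hybridisation controls the median was 0.10, with 3 members higher and 4 lower, and with the poly-A spike-ins it was -0.41, with 2 higher and 7 lower. As deposited, 16 p53 members were above 0 and 7 below. Beside POLH, those below were ZMAT3 (-0.996), TP53INP1 (-0.91), RRM2B (-0.62), MDM2 (-0.39), BAX (-0.20) and CCNG1 (-0.13). GDF15 and SESN2 are also in the ATF4 list and PMAIP1 in the BCL2 family list. Without the 5 members that other lists hold, 2 of 18 were higher and 1 lower, with a median of 0.37 at percentile 99.7. Hypoxia genes were higher in 4 of 26: the peptide hormone gene ADM (2.37), the vessel growth factor gene VEGFA (1.45), ANGPTL4 (1.40) and KDM3A (1.03). Their median of 0.44 was above all random lists (-0.11 to 0.25). It was 0.03 with the hybridisation controls, with 2 higher and 2 lower, and -0.49 with the poly-A spike-ins, with 1 higher and 3 lower.

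Oxidative stress genes of the NRF2 pathway were higher in 3 of 21: HMOX1, GCLM (1.13), an enzyme subunit of glutathione synthesis, and TKT (1.10). The other probe sets of GCLM gave -0.11 and 0.09 and those of TKT 0.36 and 0.78, all below 2-fold. OSGIN1 had 0.90. The median was 0.30, at percentile 99.1 (random lists -0.09 to 0.26), -0.13 with the hybridisation controls (1 member higher, none lower) and -0.64 with the poly-A spike-ins (1 higher, 4 lower). The call was lost with the poly-A spike-ins, with either other choice of probe sets and without members that other lists hold.

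Genes of G2 phase and mitosis were lower: 11 of 27 measured members were at least 2-fold lower, none was higher, and all 27 had a log2 ratio below 0. The kinetochore motor gene CENPE went from 1559 to 559 (-1.48), KIF20A from 3600 to 1353 (-1.41), the mitotic kinase gene PLK1 from 2771 to 1060 (-1.39) and CENPA from 2093 to 841 (-1.31). CCNB1, the mitotic cyclin B1, went from 17599 to 8509 (-1.05), and its other probe set gave -1.33. The median of -0.92 was below all 10000 random lists (-0.12 to 0.20). It was -0.88 after quantile normalisation and -0.89 after loess, with 8 members at least 2-fold lower in both, and -1.86 with the poly-A spike-ins, which lower all ratios. Genes of the G1/S transition and DNA replication had none of 22 members past 2-fold. CDC45 had 0.60, E2F1 -0.59, MCM5 0.51 and CCNE1 0.48. Their median was 0.23, at percentile 98.1, -0.20 with the hybridisation controls and -0.71 with the poly-A spike-ins. The call was lost after loess, with a pseudocount and with either other choice of probe sets.

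Genes for cytosolic ribosomal proteins shifted by little but together. None of 22 passed 2-fold, all 22 were above 0, and the median of 0.41 was above all random lists (0.02 to 0.27). It was -0.01 with the hybridisation controls and -0.53 with the poly-A spike-ins, and the call was lost after quantile normalisation, with a median of 0.02. After loess the call was kept with a smaller median of 0.14, at percentile 99.8. RPL8 had 0.53, RPL32 0.52, RPS18 0.50 and RPL10A 0.47. Glycolysis genes had none of 16 past 2-fold and all 16 above 0, with ENO2 at 0.59, PFKP at 0.53, HK2 at 0.46, ALDOA at 0.46 and GAPDH at 0.34. Their median was 0.34, at percentile 99.4, -0.08 with the hybridisation controls and -0.60 with the poly-A spike-ins. The call was lost after quantile normalisation, after loess and without members of other lists. ACTB, often used as a reference gene, had 0.41 as deposited. GAPDH and ACTB were below 0 after quantile normalisation (-0.09 and -0.01), with the hybridisation controls (-0.09 and -0.01) and with the poly-A spike-ins (-0.61 and -0.53).

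**Figure D2:**
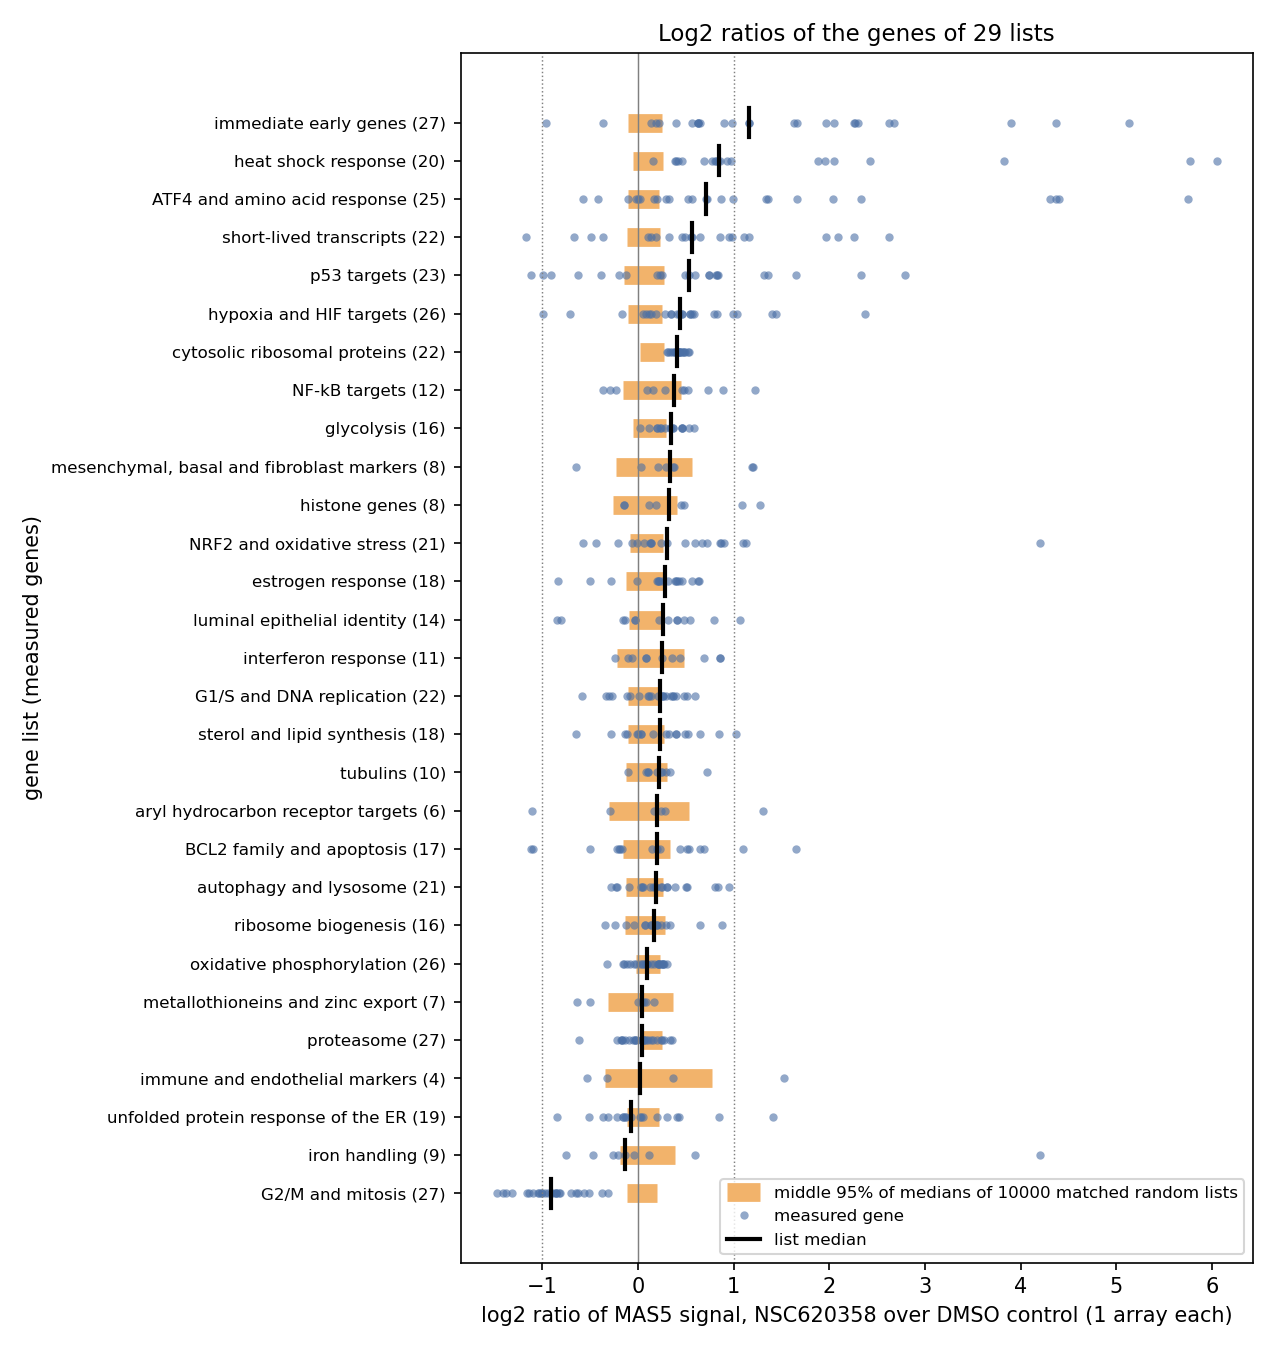
Log2 ratio of MAS5 signal, NSC620358 over DMSO (1 array each), for the measured genes of 29 lists; dots are genes, black bars list medians, orange bands the middle 95% of medians of 10000 matched random lists, and dotted lines mark 2-fold. Immediate early genes (median 1.16) and heat shock genes (0.84) lie right of their bands and G2 and mitosis genes (-0.92) left; with poly-A spike-in scaling the heat shock median is -0.06.

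In all, 10 of the 29 lists were above the middle 95% of random lists, 1 was below it and 18 were inside, the unfolded protein response among them. Estrogen response genes had none of 18 past 2-fold, with TFF1, an estrogen target, at 0.43 and MYBL1 at -0.84, and a median of 0.28 at percentile 96.8. The list was called higher after quantile normalisation (percentile 98.4), with a pseudocount (97.6) and with either other choice of probe sets (99.5 and 99.8), and was at percentile 79.8 without members of other lists. Luminal epithelial genes had SPDEF (1.06) past 2-fold among 14, ERBB3 at -0.85 and FOXA1 at -0.80, and a median of 0.26 at percentile 97.49, just inside, and it was called higher with a lower floor or none, with a pseudocount and with the poly-A spike-ins (percentiles 97.52 to 98.06). It was at percentile 37.9 after quantile normalisation, with a median of -0.016, at 78.6 after loess and at 54.9 without members of other lists. The 4 other probe sets of SPDEF above the floor on both arrays gave -0.28 to 1.29, and the other probe set of FOXA1 gave -2.25. Among mesenchymal, basal and fibroblast markers, COL1A1 (1.19) and COL1A2 (at least 2.29-fold) were higher among 8 measured, with a median of 0.33 at percentile 78.9. Among immune and endothelial markers 4 were measured and PECAM1 (1.52) was higher, although 1 other probe set above the floor on both arrays gave 0.00. Their median was 0.02 and their mean 0.26, at percentile 25, and they were called higher with a lower floor (98.1) or none (98.3). Only 4 of the 11 members with a probe set reached the floor of 66.2 on either array. Both of those calls therefore draw on signals below it.

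Among lists of signalling and cell death, NF-kB targets had RELB (1.22) higher among 12 and a median of 0.37 at percentile 92.9. Interferon response genes had none of 11 past 2-fold and a median of 0.25 at percentile 74.5. Aryl hydrocarbon receptor targets had TIPARP (1.31) higher and CYP1B1 (-1.11) lower among 6, with a median of 0.20 at percentile 64.9. The BCL2 family and apoptosis list had PMAIP1 and the death receptor gene TNFRSF10A (1.09) higher and the apoptosis inhibitor genes XIAP (-1.12) and BIRC2 (-1.10) lower among 17, with a median of 0.20 at percentile 81.7.

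Among lists of metabolism and cell structure, iron handling genes had HMOX1 higher among 9. The transferrin receptor gene TFRC had -0.76 and 2 other probe sets above the floor on both arrays -2.57 and -0.90, the ferritin gene FTL had 0.60, and the median was -0.13 against a mean of 0.34, at percentile 5.56. Metallothionein and zinc export genes had none of 7 past 2-fold, MT2A at 0.06, a median of 0.04 and a mean of -0.11, at percentile 47.2. Sterol and lipid synthesis genes had INSIG1 (1.02) higher among 18 and a median of 0.23 at percentile 92.9. Oxidative phosphorylation (26 genes, median 0.09, percentile 46.2), proteasome (27, 0.04, 6.10), ribosome biogenesis (16, 0.16, 80.9), autophagy and lysosome (21, 0.19, 88.0) and tubulin genes (10, 0.22, 89.4) had no member past 2-fold. Histone genes had H2BC11 (1.28) and H4C8 (1.09) higher among 8 and a median of 0.32 at percentile 92.1.

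Control probe sets showed how the arrays themselves differed. The poly-A spike-ins, bacterial transcripts labelled with the sample, had a median of 2.06-fold higher signal with NSC620358 over 12 probe sets (1.32 to 2.64), and the hybridisation controls, added already labelled, had 1.34-fold over 9 (1.23 to 1.53). The ratio of 3' to 5' signal, a sign of RNA and labelling quality, went from 1.22 to 1.67 for ACTB, from 0.907 to 0.978 for GAPDH and from 4.52 to 11.7 for the ISGF3A control. Over the 4 poly-A spike-in transcripts its log2 value was higher by a median of 0.31 (0.12 to 0.77), and over the 4 hybridisation controls by 0.16 (0.08 to 0.20). The 310 lower and 577 higher genes, and each list above, were compared on these same arrays.

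**Figure D3:**
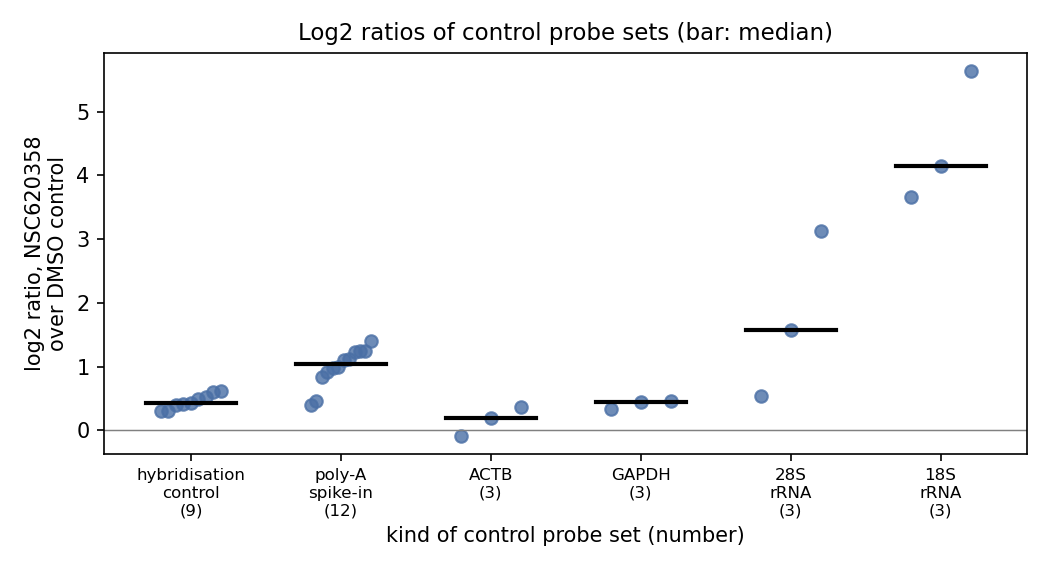
Log2 ratio, NSC620358 over DMSO (1 array each), of control probe sets by kind, with the number of probe sets in brackets; dots are probe sets and bars medians. The 18S ribosomal RNA probe sets lie between 3.65 and 5.63, above the poly-A spike-ins (0.40 to 1.40) and hybridisation controls (0.30 to 0.61). The ACTB and GAPDH control sets shown have medians of 0.20 and 0.44. The single probe sets that stand for the 2 genes elsewhere had 0.41 and 0.34 as deposited, and -0.53 and -0.61 with the poly-A spike-ins.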

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

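The tests of ribosomal RNA signal and of HSP70 relatives were chosen after the results were seen; the test of heat shock genes after the loess correction was planned before its result.

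Ribosomal RNA is outside the gene table, and most of its control probe sets had far higher signal with NSC620358. The 18S probe sets were 12.6-fold (3' end), 17.7-fold (middle) and 49.6-fold (5' end) higher, and the 28S probe sets 8.76-fold (5' end), 2.99-fold (middle) and 1.46-fold (3' end), the last within the range of the poly-A spike-ins. An array-wide difference in labelling or scaling would move the spike-ins as much, but the smallest 18S log2 ratio lay 2.25 above the largest of the spike-ins, a comparison made for 18S only. Shorter or degraded RNA may contribute and cannot be told apart: the log2 ratio of 3' to 5' signal was higher by 0.11 for GAPDH and 0.45 for ACTB. More carry-over of ribosomal RNA into the labelled sample and an effect of NSC620358 on ribosomal RNA were not tested.

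The heat shock genes were weighed because HSPA1A has no probe set of its own. Probe sets shared by HSPA1A and its relatives were 2.99-fold, 5.38-fold and 8.04-fold higher with NSC620358. Cross-hybridisation between HSP70 relatives cannot be the whole of the pattern: without the HSPA genes the median of the other 16 members was 0.82, still above all random lists. A trend of the ratio with signal cannot be either, since the median after the loess correction was 0.80. A response to NSC620358 stays a hypothesis, found and tested on the same 2 arrays without replicates.

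The poly-A spike-ins, also outside the gene table, had a median of 2.06-fold higher signal with NSC620358, and the hybridisation controls 1.34-fold. Of 11721 probe sets without a gene name, control probe sets left out, 3856 were measured, 199 (5.16%) were at least 2-fold higher and 133 (3.45%) at least 2-fold lower.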

How the results depend on the processing

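Both scalings to control probe sets and leaving out shared list members were chosen after the data were seen. Replicates could not be left out, splits of the samples could not be compared, and no paired analysis was possible because each group had 1 array. No named gene or list that was called changed to a call in the other direction under any alternative run. Of the 145 named genes' values under the alternatives, 1421 stayed on their side of 2-fold, 68 no longer passed it and 38 newly did. Of the lists' values, 322 stayed on their side, 14 lost the call and 10 gained it; median centring and both control scalings shift a list and its random lists nearly alike, so unmoved calls there show little. The spread between probe sets of a gene stayed within 1.5 times in all 10 alternatives that gave it.

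Counts of genes at least 2-fold higher and lower were 577 and 310 as deposited. They were 1989 and 1115 with the floor at the 25th percentile, 172 and 174 at the 75th percentile, 2910 and 1888 with no floor, 85 and 4177 with poly-A spike-in scaling, and 193 and 1081 with hybridisation control scaling. A 1.5-fold threshold gave 2013 and 1122, and a 3-fold threshold 122 and 33. Median centring, quantile normalisation, loess, a pseudocount and the other choices of probe sets kept both counts within 1.5 times. The genes called were not all the same ones. With a pseudocount 302 of the 577 higher and 203 of the 310 lower genes were called again. With the median over probe sets 445 and 193 were.

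List values here are the list median minus the median of its random lists, in log2. After quantile normalisation the call was lost for glycolysis (0.12) and ribosomal proteins (0.031) and gained for estrogen response (0.22). After loess it was lost for G1/S (0.11) and glycolysis (0.13). With the floor at the 25th percentile it was gained for luminal (0.19) and immune and endothelial markers (0.77), and with no floor for the same lists (0.19 and 0.89). With a pseudocount it was lost for G1/S (0.15) and gained for estrogen response (0.19) and luminal identity (0.18). With the median over probe sets it was lost for NRF2 (0.052) and G1/S (0.077) and gained for estrogen response (0.27). Without probe sets that can match several transcripts it was lost for NRF2 (0.11), p53 (0.21) and G1/S (0.028) and gained for estrogen response (0.33). With poly-A spike-in scaling it was lost for NRF2 (0.17) and gained for luminal identity (0.18). Without shared members it was lost for NRF2 (0.051), short-lived transcripts (0.25) and glycolysis (0.12), with fewer genes in each list. The cause of the other losses was not tested.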

Other observations

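Gene families in this part were chosen after their ratios were seen, as was the test of labelling toward 5' ends; the other tests were planned before their results. Because of that choice, a percentile among random lists would restate it and is not given. All 3 measured GADD45 genes, stress sensors that slow the cell cycle, were at least 2-fold higher with NSC620358: GADD45B (3.32), GADD45A (2.79) and GADD45G (1.14). GADD45A is also in the p53 list, and with either control scaling 2 of the 3 were at least 2-fold higher, with a median of 1.85 for the poly-A spike-ins. Histone demethylase genes of the KDM family were higher in 5 of 17 measured members: KDM7A (1.21), KDM5C (1.16), KDM3A (1.03), KDM5A (1.01) and KDM4D (at least 2.30-fold). Their median was 0.66, and -0.25 with the poly-A spike-ins; with the hybridisation controls none of the family was at least 2-fold higher, and with the poly-A spike-ins none was higher and 3 were lower. Clustered histone genes were higher in 9 of 35, led by H3C2 (2.24), with a median of 0.31 as deposited and of -0.42 with the poly-A spike-ins. With the hybridisation controls 3 of them were higher and none lower, and with the poly-A spike-ins 3 were higher and 5 lower. Of the 9 higher as deposited, H1-4, H2AC15, H2AC16 and H3C7 were below the floor with DMSO, so their ratios are lower bounds. H2BC17, H3C2 and H2BC11 had signals of 67.2, 69.8 and 88.3 with DMSO, near the floor of 66.2. Among DNAJ co-chaperone genes 5 of 42 were higher, namely DNAJB4, DNAJB1, DNAJA4 (1.95), DNAJB5 (1.64) and DNAJB2 (1.53), while the family median was 0.05. With the hybridisation controls 5 were higher and 4 lower, and with the poly-A spike-ins 3 were higher and 15 lower, with a median of -0.87.

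Kinesin motor genes (KIF) were lower in 7 of 33 measured members and higher in none, with a median of -0.33, of -0.32 after quantile normalisation and of -0.33 after loess. KIF11, KIF20A, KIF23 and KIF2C among the lower ones are also in the G2 and mitosis list. Genes of the CENP group had CENPI (-1.56), CENPE (-1.48) and CENPA (-1.31) lower among 18, with a median of -0.21, and CENPE and CENPA are in that list too. The SOCS genes, inhibitors of cytokine signalling, went both ways: SOCS2 (2.76), SOCS3 (2.09) and SOCS1 (1.21) were higher, and SOCS7 (-1.51) and SOCS4 (-1.22) lower, among 7, and with the poly-A spike-ins 2 were higher and 4 lower. Phosphatase genes of the DUSP family had DUSP2 (2.68), DUSP5 (1.66), DUSP1 (1.63) and DUSP10 (1.00) higher among 21, with a median of 0.37 as deposited, of -0.06 with the hybridisation controls (3 higher, 1 lower) and of -0.58 with the poly-A spike-ins (1 higher, 4 lower). Of the ZNF zinc finger genes 27 were higher and 17 lower among 368, of the KLHL genes 1 was higher (KLHL25, 1.46) and 6 lower among 27, of the SLC35 genes 3 were lower (SLC35B4, -1.84, SLC35D1, -1.75, and SLC35A3, -1.13) among 22, and of the USP genes 1 was higher (USP20, 1.74) and 1 lower (USP46, -1.96) among 40. Their medians were 0.19 (ZNF), -0.01 (KLHL), -0.07 (SLC35) and 0.06 (USP). The balance of these calls depended on the scaling: with the hybridisation controls 8 ZNF genes were higher and 33 lower, and with the poly-A spike-ins 3 were higher and 118 lower, while no USP gene was higher and 18 were lower.

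Ratios were lower in genes with a longer span on the genome. Over 10789 coding genes above the floor on both arrays, Spearman's rho of span and log2 ratio was -0.16, across genes that are not independent replicates. The 2158 genes with the shortest spans (median 5.35 kb) held 114 higher and 28 lower genes, and the 2158 with the longest (153 kb) held 55 and 68. The trend did not go on to the longest genes: median log2 ratios over the 5 groups by span were 0.20, 0.12, 0.07, -0.01 and 0.02, and the 2158 genes at a median of 59.4 kb held 62 higher and 78 lower. A trend of the ratio with signal and the fixed lists with all genes past 2-fold are not the whole of it, since rho was -0.15 after loess and -0.15 without those genes. Weaker labelling toward 5' ends with NSC620358 may contribute. Over 7 control transcripts labelled with the sample, the log2 ratio of 3' to 5' signal was higher by a median of 0.45 (0.11 to 1.37). That median lay above the 0.08 to 0.20 of the 4 hybridisation controls. GAPDH (0.11) and the poly-A spike-ins phe (0.12) and lys (0.14) lay within that range, and the ISGF3A control gave the 1.37. Span is not transcript length, and an effect of NSC620358 on long genes was not tested.

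A hypothesis was that genes called lower follow their call less in other probe sets than genes called higher. The median share of the called ratio in the other probe sets was 0.54 for 175 lower and 0.56 for 152 higher genes, a difference of -0.017 (95% bootstrap interval -0.11 to 0.13), which gave no sign of it. Another hypothesis was that signal is higher next to genes at least 4-fold higher. The 111 measured genes within 50 kb of those 55 genes had a median of 0.19, at percentile 96.5. This lay within the middle 95% of random lists (0.01 to 0.20), the outcome planned for no rise. It lay near the upper end, so a small rise is not decided. A last hypothesis was that long non-coding RNA genes are higher as a class. Their median was 0.19 over 922 genes, at percentile 90.2. This too lay within the middle 95% of random lists (0.13 to 0.20), the outcome planned for no rise, and a small rise stays open. Of the 922, 64 (6.94%) were at least 2-fold higher and 14 lower, against 4.08% of coding genes higher. That comparison of shares was not matched on signal.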
